A study of Homo sapiens with 4 samples.

How the data were processed

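Total RNA from 4 MCF7 samples (2 transfected with a green fluorescent protein construct, 2 with its fusion to alpha-synuclein) was measured, per the labels' protocols, after Trizol extraction and labelling with a biotin module for cDNA. The platform of the probe annotation is the Affymetrix HG-U133 Plus 2.0 layout. The authors deposited log2 expression values, 1 per probe set and array. GCRMA and Partek are named in the submitters' processing notes, and the versions, settings and scan batches are not given in the sources used here. GCRMA corrects background with a model of probe sequence, normalizes arrays to a common distribution and summarises the probes of a set, so dim probe sets collect near a floor and probe-level noise is no longer visible. The log2 scale of the deposited values was read from their range. Per-array medians ran from 5.72 to 5.77, and no pair of arrays shared more than 0.404% of its values. No detection calls were used here, and the number of arrays limits the precision. The labels call the samples biological replicates but do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

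From there, the analysis used R 4.3.3 and limma 3.58.1. Control probe sets (62) were set aside, and probe sets above log2 4 on at least 2 of the 4 arrays were kept (40759 of 54613). Each was fitted with lmFit and eBayes with group as the only term, 2 residual degrees of freedom and a prior worth 2.29, and p-values were two-sided and adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. SE is the moderated standard error of the log2 difference, SD the spread of the 2 arrays of a group, and fold is 2 to the power of the absolute log2 difference. Of the probe sets that are not controls, 41091 had a single gene symbol, 1801 had several and 11721 had none in the annotation. Entrez identifiers of 41037 matched a RefSeq gene table of GRCh38.p14, and 0 symbols needed an update. Only probe sets with a single symbol were named. Per gene, the probe set with the highest mean over the 4 arrays was used. Probe sets whose identifiers end in _s_at or _x_at can bind several transcripts. All 4 value columns belonged to the samples described, with 0 others in the table.

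The groups, the tests, 33 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 15 most changed genes per direction that passed, and, if fewer than 5 passed, the 10 with the smallest p per direction, leaving out provisional names. The second part applied. It also named SNCA, SNCB, SNCG, ESR1, PGR, TFF1, GATA3, CDH1, VIM, MKI67, CDKN1A and BCL2 where measured, and up to 4 members of each list with the smallest p. Lists with at least 5 measured genes (31) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. With single arrays, a list's median was set against 10000 random lists of the same size matched on mean expression in 20 bins. These were drawn gene by gene, so they lack the co-expression of real lists. The planned check of the transfected gene could not be made because the annotation used here names no probe set for it.

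The alternatives were quantile normalization, median centring, no filter, log2 above 6 on at least 2 arrays, a mean above log2 4, an intensity trend with a robust prior, a floor at log2 4, leaving out probe sets ending in _x_at or _s_at, a test without moderation, the mean of a gene's probe sets, an estimated correlation, fry, each array left out in turn, and the replicate number as a block. Array quality weights, a crossed block and cyclic loess were added after the data were seen. Replicate numbers 1 and 2 occur in both groups, but no label ties a number to a shared culture or day. The code was tested on simulated data with the means of the 40759 probe sets and 200 changed ones in each of 5 draws. Spreads were drawn from the fitted prior, and probe sets were drawn independently of each other. The median estimates were 1.01, 2.01 and 3.99 for simulated log2 changes of 1, 2 and 4. Over the 5 draws 9 unchanged probe sets were called. The proteasome list, shifted by 0.5, was found in 5 of 5 draws at the preset correlation. Its estimated correlation in the deposited data was 0.88, so this does not show how the list test behaves with correlated genes.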

Results

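Gene expression was measured by microarray in MCF7, an oestrogen receptor-positive luminal breast cancer cell line, after transfection with 1 of 2 constructs. The SNCA group (n = 2 arrays) received a construct for a fusion of emerald green fluorescent protein with alpha-synuclein, a presynaptic lipid-binding protein whose gene is SNCA. The GFP control group (n = 2 arrays) received the fluorescent protein alone, and both were selected with blasticidin. The submitters describe the SNCA material as 2 separately isolated clones and call the reference cells parental, whereas the sample labels call the controls GFP-transfected. The sample labels were followed, and which SNCA array belongs to which clone is not given. The question was which genes differ in expression when alpha-synuclein is expressed in these breast cancer cells. Each array held 54675 probe sets, with a median log2 value between 5.72 and 5.77. After removal of 62 control probe sets, 40759 probe sets exceeded log2 4 on at least 2 arrays and were tested. They covered 16195 genes with a single symbol. The labels call the arrays biological replicates without saying which came from separate cultures, and the small number of arrays limits the precision of every value.

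Progesterone receptor (PGR), a classical oestrogen receptor target, read 10.37 on GFP control 1 and 5.31 on GFP control 2, a wider gap than that between either control and either SNCA array, which read 8.26 and 9.62. The 2 control arrays were at least 2-fold apart at 4594 probe sets, or 11.3% of those tested. GFP control 1 was about as far from SNCA 1, at 4473 probe sets, and from SNCA 2, at 4352. GFP control 2 was closest to SNCA 1, at 1238 probe sets, and differed from SNCA 2 at 2578. The 2 SNCA arrays differed from each other at 2622. At 2-fold the control pair thus had the most differences of the 6 pairs, whereas at 4-fold GFP control 1 with SNCA 1 (676) and with SNCA 2 (639) exceeded it (599). When each SNCA array was compared with a different control array, the log2 differences correlated across probe sets with r = -0.12 in one pairing and r = 0.096 in the other. These are correlations across genes, which are not independent replicates, and no test was attached to them.

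**Figure D1:**
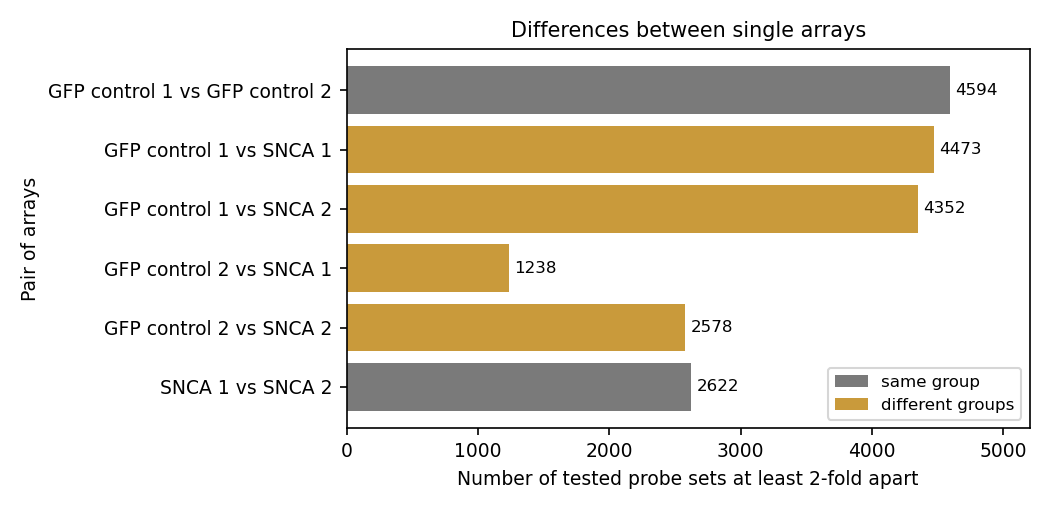
Bars give the number of tested probe sets at least 2-fold apart (x axis) for each of the 6 pairs of arrays (y axis), grey for arrays of the same group and ochre for arrays of different groups. The pair of control arrays differs at 4594 probe sets and GFP control 2 with SNCA 1 at 1238.

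The probe annotation used here names no probe set for SNCA, so no tested value could be assigned to the transfected gene. The labels were therefore not checked through it. Probe sets that the annotation does not list were tested, and whether any of them measures SNCA cannot be told from it. The smallest p-value in the comparison belonged to a probe set the annotation does not list, 211546_x_at, which read 13.74 and 13.73 on the SNCA arrays against 7.11 and 6.73 on the controls. The difference was 6.81 ± 0.22 (SE) on the log2 scale, or 112-fold. Another unlisted probe set, 207827_x_at, read 13.53 and 13.47 against 7.37 and 6.89, a difference of 6.37 ± 0.24 (SE). Both had an adjusted p of 0.0901 in the limma fit and did not pass the threshold of 0.05. They were singled out after their values were seen. Of the other synuclein genes, gamma-synuclein (SNCG), first described in breast cancer, averaged 7.10 ± 0.85 (SD, n = 2) in SNCA and 5.84 ± 0.33 in the controls at its brighter probe set, with a limma adjusted p of 1. Its other probe set differed by -0.0048. Beta-synuclein (SNCB) averaged 5.51 ± 0.45 against 5.09 ± 0.038, also with an adjusted p of 1.

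The genes with the smallest p and higher values in SNCA formed a mixed group of surface, secreted, cytoskeletal and developmental genes. CT83, a cancer-testis antigen, averaged 9.27 ± 0.16 (SD, n = 2) in SNCA and 2.91 ± 0.29 in the controls, an 82.2-fold difference. PLS3, which encodes the actin-bundling protein plastin 3, averaged 10.83 ± 0.14 against 5.06 ± 0.62, a 54.3-fold difference. CEACAM6, a cell adhesion glycoprotein of epithelial tumours, averaged 10.86 ± 0.63 against 5.85 ± 0.69, and ANKRD40CL averaged 9.98 ± 0.66 against 3.99 ± 0.10. The developmental transcription regulators SOX11 and EYA4 stood 5.74-fold and 7.48-fold above the controls. The proton-sensing receptor GPR65 stood 10.5-fold above them, the mucin gene MUC5B 5.96-fold, the exchange factor VAV1 of blood cells 5.47-fold and the neutral amino acid transporter SLC1A4 4.43-fold. For all 10 genes both SNCA arrays lay above both control arrays. None passed: the adjusted p was 0.0901 for CT83, 0.295 for PLS3, ANKRD40CL, GPR65 and EYA4, and 0.452 to 0.683 for the rest in limma's moderated test with Benjamini-Hochberg adjustment.

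Control values of CT83, ANKRD40CL, GPR65 and EYA4 were near or below log2 4, where the size of a difference depends on the background correction. With values under log2 4 set to 4, the differences became 5.27 for CT83, 5.95 for ANKRD40CL, 2.28 for GPR65 and 2.51 for EYA4. Further tested probe sets of the same genes mostly followed the chosen one, though probe sets dim in both groups were not tested. The other CEACAM6 probe set differed by 5.83 and both further SOX11 probe sets by 2.54 and 1.98. The other EYA4 probe set differed by 2.31. Its control values of 2.10 and 2.63 were under log2 4, so that size also depends on the background correction. The MUC5B probe sets were divided, with differences of 2.58 and 0.25. SLC1A4 was also divided, with its 5 probe sets lying between -0.26 and 2.42.

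Among the genes with the smallest p and lower values in SNCA, TFPI, the inhibitor of the first step of blood coagulation, averaged 7.77 ± 0.16 (SD, n = 2) in SNCA and 10.64 ± 0.057 in the controls, a 7.30-fold difference. All 5 tested TFPI probe sets were lower, with log2 differences from -3.12 to -1.55. The membrane protein gene ITM2A averaged 7.20 ± 0.24 against 9.71 ± 0.084, and its other probe set differed by -2.49. The glutathione transferase gene GSTM4 differed by -2.04 ± 0.25 (SE), although its probe sets are of kinds that can bind several members of that family. MAPK10, the JNK3 kinase, differed by -2.43 ± 0.33, with -1.45 and -0.59 at its dimmer probe sets. The former of these read 2.93 and 2.84 on the SNCA arrays and the latter 3.60 on SNCA 1. These values are under log2 4, so the 2 sizes depend on the background correction. The matrix gene PAPLN differed by -1.97 ± 0.28, with no counterpart at the other PAPLN probe set (0.10). NBEA, a vesicle trafficking protein, differed by -1.62, ZFP3 by -1.57, the antisense RNA TFAP2A-AS1 by -1.40, the MAP kinase phosphatase gene DUSP2 by -1.16 and EFHC2 by -1.65, or -0.92 with values under log2 4 set to 4. Both SNCA arrays lay below both control arrays for all 10 genes. The limma adjusted p was 0.296 for TFPI, 0.452 for ITM2A, 0.918 for ZFP3 and GSTM4, and 1 for the other 6, so none passed.

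**Figure D2:**
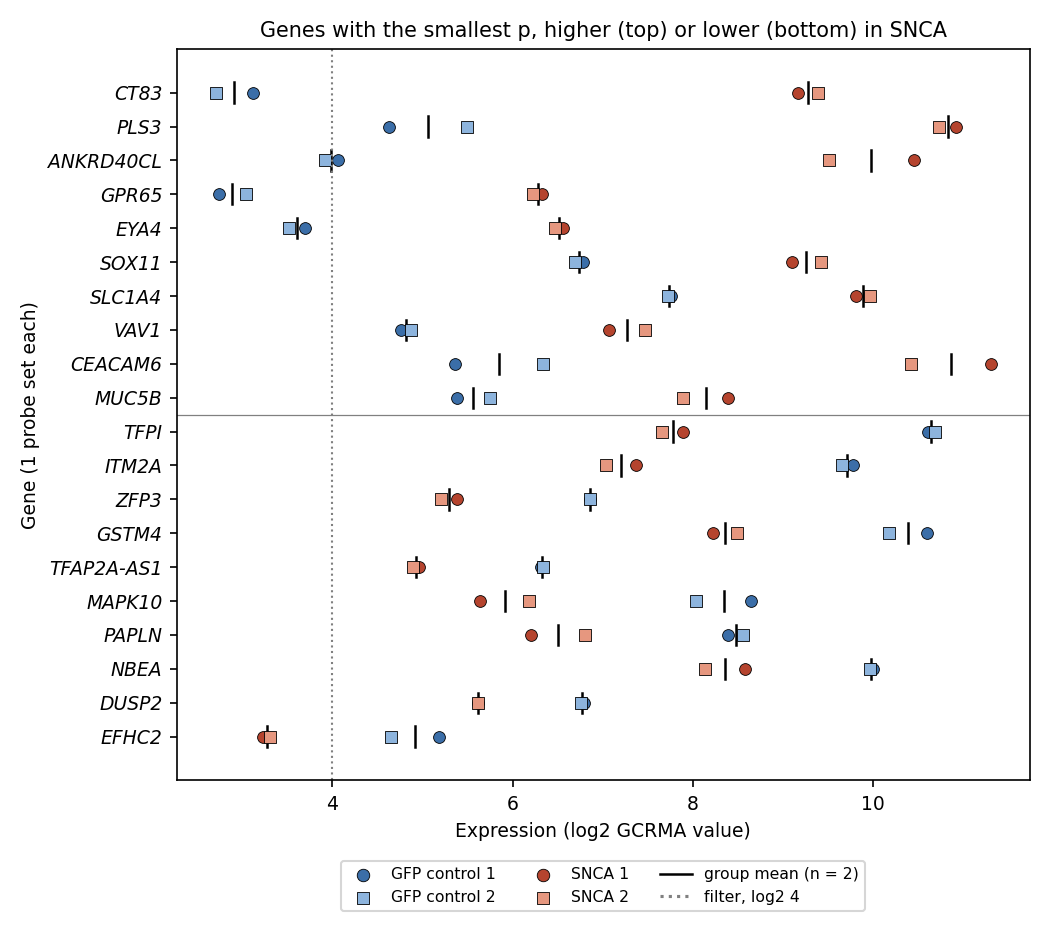
Points give the log2 GCRMA value (x axis) of each array for the 10 genes with the smallest p that were higher and the 10 that were lower in SNCA (y axis); black ticks are group means (n = 2) and the dotted line marks log2 4. CT83 lies at 3.12 and 2.71 on the control arrays and at 9.16 and 9.38 on the SNCA arrays, and none of the 20 genes passed an adjusted p of 0.05.

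Over all 40759 probe sets, 0 passed an adjusted p of 0.05 in limma and 0 did so with a change of at least 2-fold. The smallest adjusted p was 0.0901. At an unadjusted p under 0.05 there were 1348 probe sets, 797 higher and 551 lower in SNCA, fewer than the 2038 that chance would give. An ordinary test without moderation also passed 0 probe sets, and an intensity trend with a robust prior passed 1, the unlisted 211546_x_at. Simulated data of the same size had independent probe sets with spreads drawn from the fitted prior. There the fit called 44.2% of probe sets changed by 4 on the log2 scale. It called 0.299% of those changed by 2 and 0 of 335 changed by 1.

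The arrays of the groups did not overlap at 28.7% of probe sets, where chance gives 33.3%. Of the splits that cross the groups, GFP control 1 with SNCA 2 against GFP control 2 with SNCA 1 separated 42.0%. The other separated 28.9%. As a description added after this result, 55 probe sets had every SNCA array at least 4-fold from every control array, 39 higher and 16 lower. Splitting the same 4 arrays in the other ways gave 1 and 15 such probe sets. At 2-fold the order was different: 214 probe sets for the real split, and 295 for GFP control 1 with SNCA 2 against GFP control 2 with SNCA 1. By 1 probe set per gene, 29 genes with a single symbol met the 4-fold criterion, 24 higher and 5 lower. They included the adhesion gene CEACAM5, at 11.17 and 10.66 on the SNCA arrays and 5.55 and 7.45 on the controls, and the chemokine CXCL14, at 10.17 and 10.99 against 7.13 and 5.62. The aldo-keto reductase AKR1B10 read 8.62 and 8.64 against 3.39 and 5.98, so the size of its difference depended on the control array and on a value under log2 4. The morphogen SHH was 6.94-fold higher, and the fibrillar collagen gene COL3A1 read 5.89 and 6.65 against 10.30 and 8.95. None of these 5 genes, chosen after their values were seen, passed the limma test.

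The cell cycle list was the only one of 31 tested lists to pass at a preset correlation. It did not pass with an estimated one (camera adjusted p = 0.963). With an estimated correlation, camera rests on 2 residual degrees of freedom and gave every tested list an adjusted p of at least 0.963. The Wnt and Notch response moved from 0.0653 to 0.963 although its estimated correlation of -0.028 is below the preset 0.01. Here and below, a value of 0.963 therefore does not show that gene correlation undid a result. Limma's fry likewise gave every list at least 0.962. All 30 measured cell cycle genes had a higher mean in SNCA than in the controls. Their median difference was 0.25 on the log2 scale (limma's camera, preset correlation 0.01, adjusted p = 0.00058). In 9 of the 30 both SNCA arrays lay above both control arrays. No single member passed, over all genes or adjusted over the list alone. The mitotic kinase PLK1 averaged 10.08 ± 0.18 (SD, n = 2) against 9.25 ± 0.33, the S-phase transcription factor E2F1 10.05 ± 0.047 against 9.06 ± 0.59, TTK 9.69 ± 0.27 against 9.02 ± 0.59, and the proliferation marker MKI67 11.45 ± 0.12 against 10.76 ± 0.85. The list's median stood 0.47 above GFP control 1 but 0.017 above GFP control 2. At the preset correlation the adjusted p was 0.921 without GFP control 1 and 7.44e-07 without GFP control 2, and limma's fry, which asks whether a list's genes move one way without comparing them with other genes, gave 0.962.

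Oestrogen response and luminal lists did not pass, and their level followed the control array chosen. Of the 24 measured oestrogen response genes, 8 were above and 1 below both controls on both SNCA arrays, with a median difference of 0.21 and an adjusted p of 0.169. The list's median difference was 0.38 from GFP control 2 and -0.075 from GFP control 1, and without GFP control 1 its adjusted p was 1.47e-06 at the preset correlation. With all 4 arrays the adjusted p was 0.963 with an estimated correlation, for this list and for the luminal one. Among its members the scaffold gene PDZK1 averaged 9.80 against 7.37, TFF3 9.25 against 8.18, OLFM1 10.06 against 9.09 and the carbonic anhydrase CA12 10.72 against 11.66. PGR averaged 8.94 ± 0.96 (SD, n = 2) against 7.84 ± 3.57 and TFF1 13.26 ± 0.094 against 13.08 ± 0.018. The 22 luminal epithelial genes had a median difference of 0.011 (adjusted p = 0.878, or 0.0215 without GFP control 1). The oestrogen receptor gene ESR1 averaged 12.14 ± 0.12 against 12.01 ± 0.55, the luminal transcription factor GATA3 12.71 ± 0.047 against 13.04 ± 0.20, E-cadherin (CDH1) 12.80 ± 0.071 against 12.83 ± 0.055 and MUC1 12.77 ± 0.059 against 11.92 ± 0.39.

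**Figure D3:**
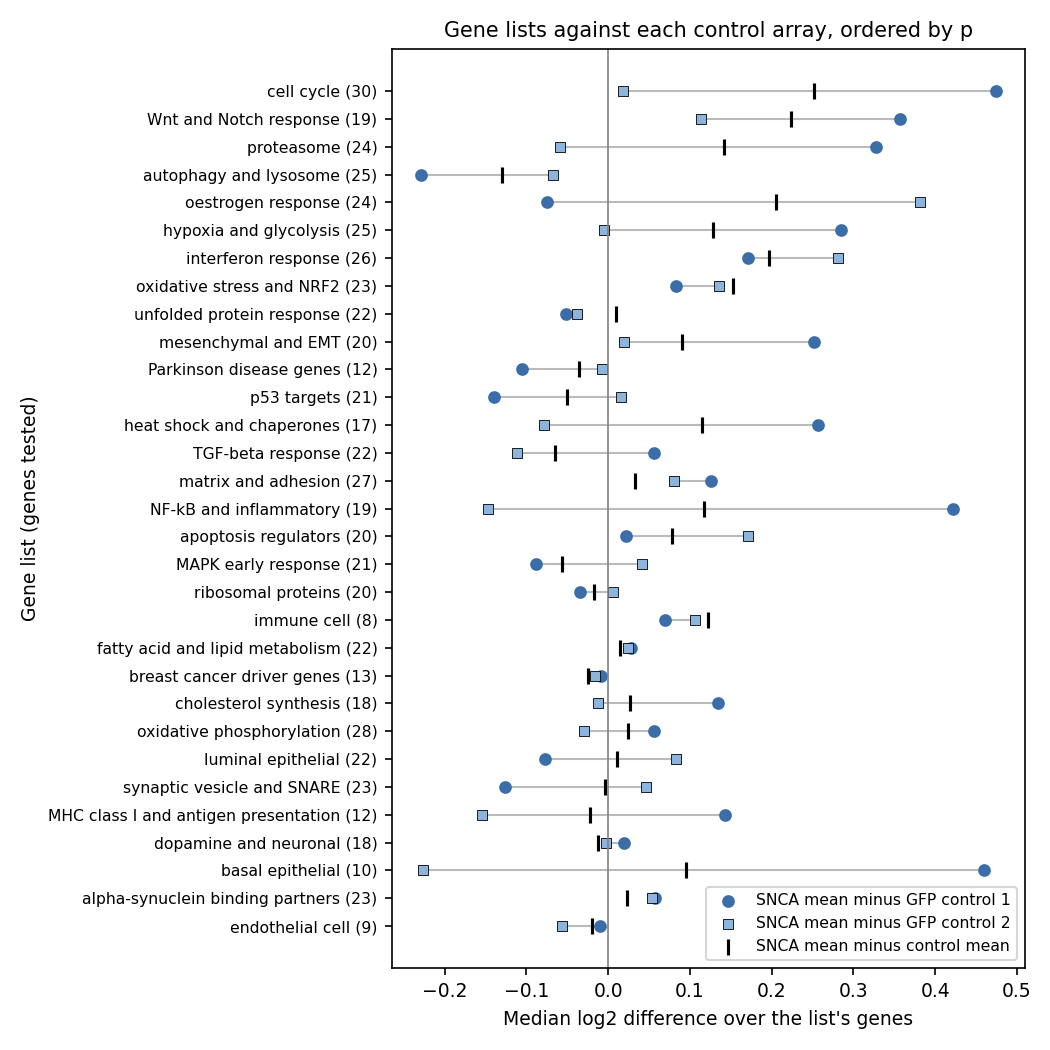
For each of the 31 tested gene lists (y axis, number of genes in brackets), points give the median log2 difference (x axis) of the SNCA mean from GFP control 1 (circles) and from GFP control 2 (squares), and ticks the difference from the control mean. The cell cycle list lies at 0.47 against GFP control 1 and at 0.017 against GFP control 2.

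Lists tied to alpha-synuclein showed no shift that passed. The adjusted p was 0.935 for 23 genes of its binding partners, 0.630 for 12 Parkinson disease genes, 0.935 for 23 synaptic vesicle and SNARE genes and 0.935 for 18 dopamine and neuronal genes. The deubiquitinase gene UCHL1 averaged 8.60 ± 0.18 (SD, n = 2) against 6.99 ± 1.62, the kinase PLK2 11.07 ± 0.30 against 11.68 ± 0.30, and the auxilin gene DNAJC6 differed by -0.78. The granin-processing gene SCG5 differed by 1.59, the secretogranin SCG2 by 1.24, the microtubule protein MAP2 by -0.88 and synaptophysin (SYP) by -0.50. None of these members passed over all genes or adjusted over the list alone.

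Protein quality control, stress and metabolic lists also stayed above the threshold. All 24 proteasome genes had a higher mean in SNCA, with a median difference of 0.14 and an adjusted p of 0.0949, but the list's median was 0.33 against GFP control 1 and -0.058 against GFP control 2. Its adjusted p was 0.00309 with an intensity trend and robust prior, 0.00080 without GFP control 2 and 0.0151 without SNCA 2, all at the preset correlation. With all 4 arrays and an estimated correlation it was 0.963. The adjusted p was 0.162 for autophagy and lysosome (median -0.13), 0.169 for hypoxia and glycolysis, 0.630 for the unfolded protein response, 0.630 for heat shock and chaperones and 0.630 for oxidative stress and NRF2. It was 0.854 for oxidative phosphorylation, 0.854 for cholesterol synthesis, 0.850 for fatty acid and lipid metabolism and 0.850 for ribosomal proteins. Autophagy and lysosome passed without GFP control 2 (0.0239) or SNCA 2 (0.0101), hypoxia and glycolysis without GFP control 2 (0.0173), and fatty acid and lipid metabolism without SNCA 1 (0.0364), at the preset correlation. With all 4 arrays each had an adjusted p of 0.963 with an estimated correlation. The stress transcription factor ATF3 averaged 7.07 ± 0.19 (SD, n = 2) against 8.04 ± 0.070, asparagine synthetase (ASNS) 11.05 against 11.72, the lipid-binding protein gene FABP5 10.10 ± 0.28 against 7.05 ± 2.64 and the triglyceride synthesis gene DGAT2 7.74 against 6.15.

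Signalling lists gave the Wnt and Notch response an adjusted p of 0.0653 over 19 genes, with a median difference of 0.22. At the preset correlation it passed without a filter (0.0255) and without SNCA 2 (0.0130), and its adjusted p was 0.963 with an estimated correlation and all 4 arrays. AXIN2, a standard target of Wnt signalling, differed by 1.53 ± 0.34 (SE), the Notch ligands JAG1 and DLL1 by 1.04 and 0.54, and the Wnt antagonist DKK1 by -0.74. The adjusted p was 0.630 for the TGF-beta response, 0.850 for the MAPK early response, 0.491 for the interferon response, 0.649 for NF-kB and inflammatory genes, 0.935 for MHC class I and antigen presentation, 0.630 for p53 targets and 0.850 for apoptosis regulators. The interferon response passed without SNCA 1 (0.0364) and the NF-kB list without SNCA 2 (0.0357), at the preset correlation. With all 4 arrays both had an adjusted p of 0.963 with an estimated correlation. Lipocalin 2 (LCN2), an iron-siderophore binding protein, averaged 9.05 ± 0.40 (SD, n = 2) against 6.28 ± 0.72. Its p was 0.0462 adjusted over the list alone and 1 over all probe sets in limma. It was the only member of any list to pass that narrower adjustment. CCN2 differed by 1.76, ID3 by -0.98, EGR3 by 2.09 and SAMD9 by 1.69, with no pass in either adjustment. The p53 target CDKN1A differed by -0.011 and BCL2 by -0.14, while another BCL2 probe set differed by 2.29. With 1 array left out the BCL2 difference at its brightest probe set ran from -0.25 to -0.030.

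Lists for other cell types did not pass. The adjusted p was 0.630 for 20 mesenchymal genes, 0.935 for 10 basal epithelial genes, 0.850 for 8 immune cell genes and 0.994 for 9 endothelial genes, and 0.850 for 13 breast cancer driver genes and 0.649 for 27 matrix and adhesion genes. Within the mesenchymal list COL3A1 averaged 6.27 ± 0.54 (SD, n = 2) against 9.62 ± 0.96, the transcription factor TWIST1 6.08 against 4.43, smooth muscle actin (ACTA2) 10.05 against 8.41 and vimentin (VIM) 7.59 ± 0.42 against 6.75 ± 0.30. In the matrix and adhesion list the protease MMP9 differed by 1.36 and the adhesion molecule L1CAM by -1.23. In the immune list the actin regulator CORO1A averaged 8.29 against 6.92. In 6 lists far from the threshold the median, the mean and the test differed in sign: Parkinson disease genes (median -0.035, mean 0.036, lower by test), dopamine and neuronal (-0.012, 0.11, higher), endothelial cell (-0.020, 0.0085, higher), MHC class I (-0.022, 0.047, lower), the unfolded protein response (0.0094, -0.081, lower) and the MAPK early response (-0.056, 0.045, lower). The synuclein family and the cancer-testis antigens had 2 and 3 measured genes and were not tested as lists. The cancer-testis members CTAG2, PAGE1 and PAGE4 differed by -0.093, -0.32 and 0.096.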

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

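Array quality weights, the crossed block, cyclic loess and all counts of probe sets at least 4-fold apart were chosen after the data were seen. Without GFP control 1 the cell cycle list, the only list past the threshold, ended with an adjusted p of 0.921 (median 0.017), while the oestrogen response (1.47e-06, median 0.38) and luminal epithelial (0.0215) lists passed. In the other settings that compare lists with other genes at the preset correlation the cell cycle list passed, at 7.44e-07 without GFP control 2 to 0.0364 without SNCA 1. The number of lists past the threshold was 1 in the reported setting, 2 without a filter (Wnt and Notch response added, 0.0255), 2 with an intensity trend and robust prior (proteasome added, 0.00309), 0 with an estimated correlation and 0 with fry, and 2 to 5 over the fits that left out 1 array, where a group of 1 array is assumed to vary like the other. Probe sets past the threshold numbered 0 in all settings but the intensity trend with a robust prior, which gave 1, at least 2-fold changed, with an adjusted p of 0.0482 (211546_x_at). Their smallest adjusted p otherwise ran from 0.0509 (log2 above 6) to 1. Probe sets at least 4-fold apart, 39 higher and 16 lower, were 21 and 8 without _x_at and _s_at probe sets, which leaves fewer to count, and 50 to 182 and 30 to 100 with 1 array left out, which by construction loosens the criterion (66 and 42 without GFP control 1, 182 and 100 without GFP control 2). For the pairs control 1 with control 2, control 1 with SNCA 1, control 1 with SNCA 2, control 2 with SNCA 1, control 2 with SNCA 2, and SNCA 1 with SNCA 2, the counts were 11319, 11228, 10743, 4464, 7630, 7737 at 1.5-fold and 599, 676, 639, 161, 330, 193 at 4-fold. With 1 array left out, the log2 difference of CDH1 ran from -0.079 to 0.022, CDKN1A from -0.20 to 0.18, ESR1 from -0.27 to 0.52 and PGR from -1.43 to 3.63, so the sign of the difference of these 4 depended on the array left out. Those of BCL2 (-0.25 to -0.030), GATA3 (-0.47 to -0.19), MKI67 (0.082 to 1.29), SNCB (0.098 to 0.74), SNCG (0.65 to 1.86), TFF1 (0.11 to 0.25) and VIM (0.54 to 1.13) kept their sign but moved in size. For BCL2 this holds for its brightest probe set. The 20 genes of smallest p kept their direction in every setting that tested them, which their choice largely fixed. For each, both SNCA arrays lay on the same side of both controls, so leaving out an array cannot turn the sign. Over all settings, named genes and probe sets kept direction and side in 486 of their values, and lists in 465, with 44 turned, 13 newly past the threshold and 3 no longer past it. For the lists whose direction turned the cause was not tested. Their adjusted p was, with median centring endothelial cell 0.969; with log2 above 6 on at least 2 arrays synaptic vesicle and SNARE 0.914, basal epithelial 0.803, cholesterol synthesis 0.914; with replicate block alpha-synuclein binding partners 0.92, endothelial cell 0.905; with mean of a gene's probe sets alpha-synuclein binding partners 0.971, MHC class I and antigen presentation 0.97, oxidative phosphorylation 0.993; with fry synaptic vesicle and SNARE 0.999, MHC class I and antigen presentation 0.999; with cyclic loess normalization alpha-synuclein binding partners 0.961. With 1 array left out it ran over these ranges: alpha-synuclein binding partners 0.857 to 0.921, apoptosis regulators 0.359 to 0.977, basal epithelial 0.475 to 0.891, breast cancer driver genes 0.658 to 0.998, cholesterol synthesis 0.359 to 0.959, dopamine and neuronal 0.612 to 0.921, endothelial cell 0.455 to 0.921, fatty acid and lipid metabolism 0.0364 to 0.921, heat shock and chaperones 0.0928 to 0.969, hypoxia and glycolysis 0.0173 to 0.921, interferon response 0.0364 to 0.998, luminal epithelial 0.0215 to 0.911, MAPK early response 0.359 to 0.921, MHC class I and antigen presentation 0.446 to 0.998, NF-kB and inflammatory 0.0357 to 0.664, oestrogen response 1.47e-06 to 0.663, oxidative phosphorylation 0.716 to 0.998, p53 targets 0.359 to 0.921, proteasome 0.00080 to 0.891, ribosomal proteins 0.663 to 0.959, synaptic vesicle and SNARE 0.663 to 0.969, TGF-beta response 0.182 to 0.998. With the replicate block 0 probe sets and 1 list passed the adjusted threshold, as without it, and 1184 probe sets (670 higher, 514 lower) had an unadjusted p under 0.05, against 1348 (797 and 551) without it. Deviations of same-numbered arrays from their group means correlated at r = -0.20. With 2 arrays per group this equals a correlation of the same size and opposite sign for differently numbered arrays. It cannot show whether the numbers mark a shared culture or day. Crossed pairing gave 0 probe sets past the adjusted threshold and 1920 (1113 higher, 807 lower) at an unadjusted p under 0.05. On simulated data 0.299% of log2 changes of 2 were called, and values near log2 4 limit what can be read from dim probe sets.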

Other observations

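The tests of RNA degradation, hybridization controls, the cell cycle list, the other splits and dilution, and all values between single arrays, were chosen after the results were seen. Genes named with values for single arrays were picked for the size of their difference.

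The 2 control arrays differed in many lists, among them oestrogen response and cell cycle. The random lists used as a scale lack the co-expression of such lists, whose estimated correlations were 0.389 and 0.654. Between 2 single arrays a co-expressed list leaves their range easily. Extreme percentiles therefore do not measure how unusual a shift is. On GFP control 1 the oestrogen response list had a median 0.66 above that on GFP control 2, higher in 21 of 24 genes and above all 10000 random lists (percentile 100). PGR read 10.37 and 5.31, KRT13 8.43 and 6.30, and PDZK1 8.27 and 6.47. The luminal epithelial list was higher by a median of 0.25, in 20 of 22 genes (percentile 100), with the anterior gradient gene AGR3 at 11.02 and 4.46. The cell cycle list was lower on GFP control 1 by a median of -0.48, in 29 of 30 genes (percentile 0), and the proteasome list by -0.40, in 24 of 24 (percentile 0). MKI67 read 10.16 on GFP control 1 and 11.37 on GFP control 2, and the licensing factor CDC6 6.85 and 8.35. The NF-kB and inflammatory list differed by -0.54 (percentile 0), with CXCL8 at 4.33 and 6.72. Heat shock and chaperones were lower on GFP control 1 in 15 of 17 genes (-0.37, percentile 0.04) and hypoxia and glycolysis in 20 of 25 (-0.29, percentile 0.74), while autophagy and lysosome (0.15, percentile 98.6) and p53 targets (0.21, percentile 97.51) were higher. Basal genes went both ways, 7 of 10 lower on GFP control 1, with a median of -0.36 inside the central 95% of random lists (-0.37 to 0.32). S100A2 read 6.38 and 10.05 and EGFR 5.71 and 8.59, while KRT15 read 10.13 and 7.68.

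The 2 SNCA arrays also differed in lists, while the cell cycle list's median difference between them was -0.017 (percentile 60.1). On SNCA 2 the interferon list was higher in 22 of 26 genes (SNCA 1 minus SNCA 2, median -0.47, percentile 0.04), fatty acid and lipid metabolism in 19 of 22 (-0.38, percentile 0.01), cholesterol synthesis in 16 of 18 (-0.30, percentile 0), the oestrogen response in 19 of 24 (-0.39, percentile 0) and autophagy and lysosome in 23 of 25 (-0.32, percentile 0). IFITM1 read 7.21 on SNCA 1 and 8.58 on SNCA 2, HERC6 6.67 and 8.03, the sterol regulator SREBF1 8.13 and 9.06 and the fatty acid receptor CD36 3.52 and 5.77. SNCA 1 was higher in basal epithelial genes (0.48, percentile 100, 7 of 10), NF-kB and inflammatory genes (0.32, percentile 100, 16 of 19), the MAPK early response (0.24, percentile 100, 12 of 21), the TGF-beta response (0.13, percentile 99.4, 12 of 22) and the proteasome (0.073, percentile 99.8, 18 of 24), with RELB at 6.12 and 5.06. The same arrays were the extremes of the 3' to 5' controls, with actin at 0.68 on SNCA 1 and 1.48 on SNCA 2 and GAPDH at 0.033 and 0.178. These values describe single arrays and carry no test, and the same limit of the random lists applies to their percentiles.

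The first pattern weighed is the distance of GFP control 1 from the other arrays. RNA more degraded than on every other array is argued against. The actin 3' probe set exceeded the 5' one by 1.12 on that array and by up to 1.48 on another (SNCA 2), and GAPDH by 0.123 and up to 0.178. Both values were still above those of GFP control 2 (0.993 and 0.108) and SNCA 1 (0.682 and 0.033). With actin and GAPDH alone, some degradation on GFP control 1 cannot be excluded. A smooth intensity bias left in the deposited, already normalized values is argued against. After cyclic loess 4519 probe sets stayed 2-fold apart between the controls, against 2633 between the SNCA arrays. A bias that the earlier normalization had removed or altered would not show in this test. Dim-probe noise is argued against because 9.64% of the 15493 brightest probe sets (mean above log2 8) were 2-fold apart, against 2.60% between the SNCA arrays. The bacterial bioB and bioC hybridization controls read 0.43 higher on GFP control 1 than the mean of the other 3 arrays, which lay within 0.015 of each other. The brighter bioD and cre controls differed less. AFFX-BioDn-3_at read 13.77 on GFP control 1 and 13.58 on GFP control 2, and AFFX-CreX-3_at 14.44 and 14.51. A separate hybridization or a different amount of target may contribute and remains open. Whether it could give differences as large as that of PGR was not tested. No biological explanation was tested, because both arrays carry the same group label.

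The second pattern is the cell cycle list, which passed at the preset correlation but not with an estimated one (camera adjusted p = 0.963, or 0.962 with fry). Neither of the latter 2 settings gave any list an adjusted p under 0.962, so they do not weigh on the call. Against GFP control 2 alone the cell cycle list's median was 0.017 (82.6th percentile of random lists), and against GFP control 1 alone 0.47 (percentile 100). The call is consistent with the low cell cycle level of GFP control 1 as its source, rather than a level shared by both SNCA arrays against both controls. An effect of alpha-synuclein on the cell cycle stays open and was not tested further.

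The third pattern is the group of 29 genes at least 4-fold apart between the SNCA and control arrays. For 17 of these genes 33 further probe sets were tested, with the same sign as the chosen one in 31. Their median difference in the direction of the chosen one was 1.98 (bootstrap interval 1.16 to 2.54). Only probe sets above log2 4 on at least 2 arrays counted, so a further probe set that stayed dim in both groups was left out. The values therefore lean toward agreement. They do not settle whether single probe sets are at fault, and the remaining genes had no other tested probe set. Dilution by cells without luminal genes is argued against for the 5 lower genes. The luminal list's median was 0.011, where such a dilution would need a large fall. Cells that share the luminal genes would not show in this test. A gain or loss of chromosome regions is argued against as the whole cause for most of the 29 genes. The 2 nearest tested genes on each side had a median of 0.12 (bootstrap interval 0.057 to 0.19). This median pools all 29 genes, so it cannot weigh a gain or loss at some of them, which remains open. With 3 splits of 4 arrays, of which 1 gave as many as 55 probe sets and the highest other gave 15, no share under 0.05 can be reached. Alpha-synuclein itself, the choice of single clones and other cells as a source of the higher genes remain open and may all contribute, since the SNCA material is described as isolated clones. Dilution of the lower genes by other luminal cells also remains open.

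The neighbours' median of 0.12 still lay above 0.067, the upper end of the central 95% of 1000 random draws. Their quartiles were -0.051 and 0.61. A candidate explanation is that some of the 29 genes share a neighbourhood. PLS3, SLC6A14 and CT83 follow one another among tested genes in the GRCh38.p14 order. SLC6A14 averaged 9.51 ± 1.44 (SD, n = 2) in SNCA and 5.33 ± 1.99 in the controls, beside a log2 difference of 5.76 for PLS3 and, with values under log2 4 set to 4, of 5.27 for CT83. CEACAM5 (4.42 ± 0.70, SE) and CEACAM6 (5.01 ± 0.48) are neighbours in the tested order and related in sequence. HOXB2 (2.48) and HOXB3 (2.57) are parted by HOXB-AS1 (1.86), while HOXB4 (0.27) and HOXB-AS3 (0.28) follow HOXB3. TFPI and COL3A1, both lower, lie on either side of GULP1, which differed by -0.70, but COL5A2, next to COL3A1, differed by 0.76. Medians of the neighbours, in the direction of the gene, were also raised for KLK11 (0.79), TRPM6 (0.63), S100A7 (0.57) and TNFSF15 (0.51). They were negative for MUC5B (-0.43), SLC1A4 (-0.33), VAV1 (-0.11) and GATM (-0.059). Beside KLK11 the spread was wide. KLK8 differed by 1.48 ± 0.65 (SE) and KLK12 by 0.11. The groups overlapped at KLK10, with 6.70 and 3.94 on the control arrays and 5.71 and 8.11 on the SNCA arrays. These runs and medians were noticed in the data and were not tested one by one.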
